A study of Mus musculus with 36 samples.

How the data were processed

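Gene expression was measured by RNA sequencing in 3 mouse lymphoma cell lines, AH47A, 287 and 621. Their labelled background is Em-myc, a Myc transgene driven by an immunoglobulin enhancer that gives B cell lymphomas. Each line expressed 1 of 5 mutant TRP53 proteins, labelled G280, I192S, R246Q, R270H and V170M, or a negative control. Each was sampled untreated and after nutlin-3a. This gave 36 libraries in 12 groups of construct and treatment, with 1 library from each line in every group (n = 3 per group). Per the labels' protocols, treated cultures received 5 µM nutlin-3a, a small molecule that blocks the binding of MDM2 to p53, for 12 hours. They also received 25 µM QVD-OPH, which inhibits caspases broadly. Whether untreated cultures received the inhibitor is not given in the sources used here. RNA was taken up in Trizol, purified on RNeasy columns and made into Illumina libraries, per the labels' protocols.

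The deposited values were raw counts of reads per gene for 27179 mouse genes, identified by NCBI gene number. Per the submitters' processing notes, bcl2fastq 1.8.4 and featureCounts (without a version) were used with the mouse builds mm10 and GRCm38, which are names of the same assembly. The aligner, the gene annotation and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart. The genes G6pd2, Oas1a, Bcl2a1b, Bcl2a1d, Hbb-b1, Vpreb1, Vpreb2, Igkv8-28 and those of the Ifna family have near-identical copies, so that their counts are uncertain. The design text calls the expressed proteins human, while reads were counted on mouse genes. Counts on the mouse Trp53 gene can hold both endogenous and construct transcripts. Before treatment they were higher in the mean of 5 mutants than in the control (log2 2.33, edgeR adjusted p = 9.86e-08). That argues against a construct that these counts miss altogether. Whether its sequence is mouse or human, and how much of it the counts capture, cannot be read from the table. All 36 per-sample count columns were identical to the columns of the table of the whole series. Identifiers without a symbol (859 genes, 0.303% of all counts) were kept under their number, and 118 of them were tested. Gene coordinates were taken from the RefSeq annotation of GRCm38.p6 by NCBI gene number, which matched 25275 of the 27179 genes and 11988 of those tested, and are 1-based.

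Counts were analysed with edgeR 4.0.16 in R 4.3.3 after TMM normalization. Genes were tested where filterByExpr, with a minimum count of 10, kept them over the 12 groups. This left 12321 genes holding 99.94% of the counts and set 14858 aside. One quasi-likelihood model (robust dispersion and robust glmQLFit) held the 12 groups and cell line as an additive term over all 36 libraries, so that all comparisons share 1 estimate of the spread. Its biological coefficient of variation was 16%, on 22 residual degrees of freedom. For every mutant, 4 comparisons were read from it. The nutlin response is nutlin minus untreated, and the response difference is the mutant's response minus the control's. The untreated difference and the difference under nutlin are each mutant minus control. The differences from the control were also read for the mean of the 5 mutants. F tests asked whether the 5 mutants differ in response or when untreated. In a model with a term for line by treatment, another F test asked whether the 3 lines differ in response, with the constructs as replicates within a line. P-values were adjusted by Benjamini and Hochberg over the genes tested. A call means an adjusted p under 0.05, and every adjusted p without another tool's name is from edgeR. Log2 fold changes are given as estimate ± standard error. Normalised expression is given as CPM, the count scaled by the TMM library size, as mean ± SD over the 3 lines. The p-values measure the spread of the libraries of these 3 lines that the model leaves over, and the labels name no independent repeat of a line. The additive model counts the libraries of a line as independent, although they share that line's response to nutlin. Its p-values for a nutlin response, which rests on 3 lines, can therefore be too small. Every mutant is set against the same 3 control libraries of a treatment, so comparisons of different mutants share their chance values, and no overlap or correlation between them is given.

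Untreated and treated libraries, and constructs, were paired through the cell line their labels name. The pairing was checked on the deviations of log2 CPM from the group means. Libraries of the same line deviated together in all 198 pairs (r from 0.629 to 0.929). The use of the model with a term for line by treatment, planned for the F test of the lines, for the other comparisons was added after the data had been seen, because the lines turned out to respond differently. It is called the line-specific response fit here. Its biological coefficient of variation was 9.68% on 20 residual degrees of freedom, and its standard errors hold for these 3 lines and not for lines in general. No 2 libraries were alike within sampling noise: the chi-square per degree of freedom between libraries of the same line and treatment was 1.88 to 22.9 over 90 pairs.

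There were 22 gene lists. Of these, 6 held wild-type p53 targets acting in cell cycle arrest, apoptosis, feedback on p53, DNA repair and metabolism, and other described targets. Further lists held mitosis genes, DNA replication genes (E2F targets), MYC targets with ribosome biogenesis, ATF4 stress response genes, type I interferon response genes, NF-kB targets and the BCL2 family. Mevalonate and sterol synthesis genes and proteasome subunits were taken as described targets of mutant p53. Early B lineage, mature B cell and plasma cell genes stood for stages of the B lineage. Markers of T cells, myeloid cells, erythroid cells and fibroblasts stood for other cell types that a culture could hold. Each list was tested with camera (limma 3.58.1, on voom values in the same design, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation between the genes and fry, which asks whether the genes of a list move on balance one way, stand beside it. Calls of the members are also given adjusted over the list alone. For each line, list medians were taken from log2 CPM with a prior count of 2. The retained response of a mutant is the median, over the p53 targets of the 6 p53 lists that rose in the control, of its log2 response as a percent of the control's. Fold changes of genes with 0 counts in all 3 untreated control libraries are lower bounds against a floor of 3 counts over the group. Genes with 1 to 3 counts are given as a ratio with its exact 95% interval. Floors and intervals cover counting error only.

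The lists, the models, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes Trp53, Cdkn1a, Mdm2, Ccng1, Bbc3, Pmaip1, Bax, Myc and Bcl2l11. Per main comparison it takes the 10 called genes with the largest rise and the 10 with the largest fall (in F tests the 10 with the lowest p). These have a mean log2 CPM of at least 2 and 1 sign in all 3 lines, and predicted genes, pseudogenes and antigen receptor segments are left out. Per mutant and kind of comparison it takes the 3 such genes with the lowest p in each direction, and per list up to 4 members with the lowest p. Other genes that the text names were chosen after their values were seen, and are named as such. Some genes that the rule takes are not reported here. Alternatives tried were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors in place of TMM, no filter on low counts and no term for cell line (no block). Others were a fit of only the groups compared, leaving out each line and each library in turn, and a slope through the origin for the retained response. The line-specific response fit and a retained response computed on CPM increments or on log2 CPM means with a prior count of 2 were added after the data had been seen. Splits of the libraries into other groups of the same sizes were refitted, 10 for 3 against 3 libraries and at most 100 drawn otherwise. Permutation tests across genes used 100000 resamples.

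The steps were tested on simulated counts with the means and library sizes of these libraries, in which 100 genes changed 1.5-fold and 100 genes 2-fold. For the nutlin response of the control, 38% of the 1.5-fold and 73% of the 2-fold changes were recovered among 12126 genes, with 14 false calls. Apart from the changed genes, this simulation held line effects and independent noise, and no response to nutlin that differs between lines. Its 14 false calls therefore do not tell how many to expect in the real libraries, whose lines responded differently. For the response difference over the 5 mutants, 25% and 72% were recovered among 12220 genes with 3 false calls, and 49% and 85% with 11 false calls in the line-specific response fit. For the difference under nutlin over the 5 mutants, 54% and 88% were recovered among 12215 genes with 2 false calls, and 74% and 93% with 17 false calls in the line-specific response fit. Library totals lay between 5404113 and 10718302 counts, so small changes of weakly expressed genes are not detectable at this depth.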

Results

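RNA sequencing compared 3 mouse lymphoma lines of Em-myc background (AH47A, 287 and 621) that expressed 1 of 5 mutant TRP53 proteins or a negative control. Each was measured before and after nutlin-3a, which frees wild-type p53 from its inhibitor MDM2. All treated cultures also received the caspase inhibitor QVD-OPH, and whether untreated cultures did is not given. What is called a nutlin response below can therefore hold effects of the caspase inhibitor as well. The design asks how each mutant protein changes the response of these cells to the activation of their own p53. The 36 libraries held 5404113 to 10718302 counts, with a median of 8472640 in the 18 untreated and 7364608 in the 18 nutlin libraries. Each of the 12 groups of construct and treatment had 1 library per line (n = 3). Libraries separated by cell line before they separated by treatment. Line accounted for 0.98 of the variance of the first principal component (37.9% of the total), and treatment for 0.591 of that of the third (16.8%).

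Trp53, the gene of the expressed protein, was higher in every mutant than in the control before treatment. Its level was 238 ± 46.4 CPM (mean ± SD, n = 3) in untreated control cells, 1310 ± 580 with G280, 1160 ± 520 with I192S, 1110 ± 230 with R246Q, 998 ± 214 with R270H and 1640 ± 850 with V170M. The difference passed the test in each mutant, with adjusted p from 7.32e-08 in V170M to 1.41e-05 in R270H. Without the block for cell line the untreated call was lost for I192S (adjusted p = 0.0904), R246Q (adjusted p = 0.131) and R270H (adjusted p = 0.335). With only the groups compared it was lost for G280 (adjusted p = 0.54), I192S (adjusted p = 0.785) and V170M (adjusted p = 0.852). The mean of the 5 mutants was 5.02-fold the control (2.33 ± 0.20, adjusted p = 9.86e-08). The log2 difference was 2.14 in AH47A, 2.55 in 287 and 2.24 in 621. After nutlin the levels were 335 ± 97.5 CPM in the control and 966 ± 308, 871 ± 275, 795 ± 156, 681 ± 204 and 1360 ± 626 CPM in the mutants, in the same order. The difference under nutlin passed the test in G280 (1.52 ± 0.22, adjusted p = 0.00353), I192S (1.38 ± 0.22, adjusted p = 0.0149), R246Q (1.27 ± 0.22, adjusted p = 0.03) and V170M (1.99 ± 0.23, adjusted p = 2.9e-05). In R270H it was 1.05 ± 0.22, adjusted p = 0.149. Without line 287 the untreated call of I192S was lost. Under nutlin no call of Trp53 held without the block (adjusted p from 0.446 in V170M to 1 in the others, 0.605 in the mean of 5), that of I192S was lost with only the groups compared (adjusted p = 0.259) and that of R246Q without a filter on low counts (adjusted p = 0.061). Each of the 9 leave-outs of a line or of 1 of its own or the control's libraries ended the call of R246Q. That of I192S ended without any line, its own AH47A library, or the control's AH47A or 287 library. Those of V170M and the mean of 5 ended without 621, and that of G280 without 621 or the control's AH47A library. The Trp53 gene (NCBI gene 22059) lies on chromosome 11, 69580348 to 69591873 of GRCm38, and reads from the endogenous gene and from the construct are not told apart by the counts.

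**Figure D1:**
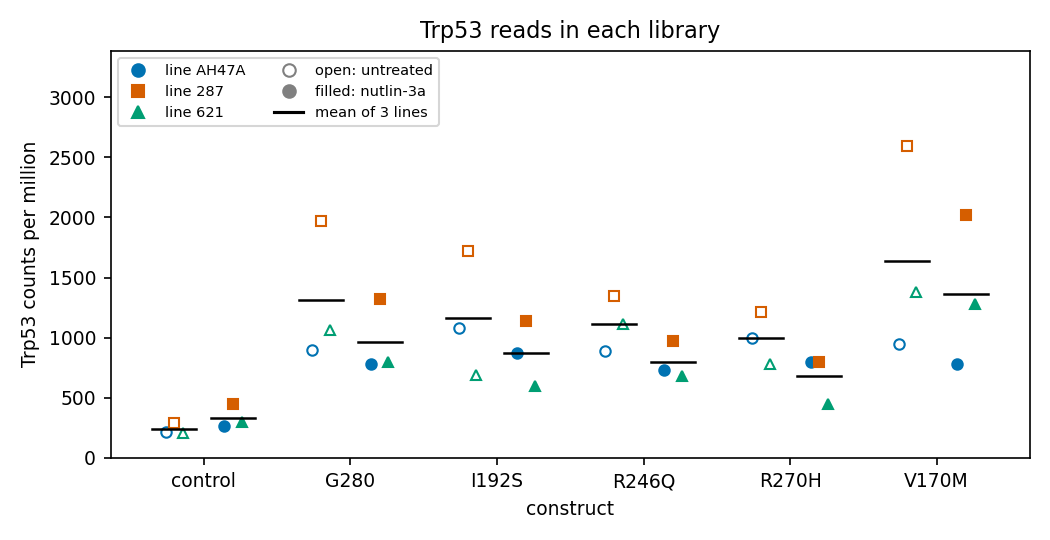
Trp53 expression in CPM in each library, by construct (5 mutants and the control); open points are untreated and filled points nutlin-treated libraries, the 3 lines have their own markers, and the short bars are means of the 3 lines. Untreated means range from 998 to 1640 CPM in the mutants and lie at 238 CPM in the control.

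Nutlin raised the best known p53 targets of the control cells strongly. Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 4.18 ± 2.72 to 413 ± 186 CPM (97.8-fold, log2 6.61 ± 0.51, adjusted p = 5.18e-10). Mdm2, the ubiquitin ligase that degrades p53, went from 111 ± 51.1 to 741 ± 588 CPM (5.9-fold, log2 2.56 ± 0.28, adjusted p = 1.84e-07). The genes of the BH3-only death proteins NOXA and PUMA rose by 6.18 ± 0.45, adjusted p = 1.92e-10 (Pmaip1) and 4.83 ± 0.74, adjusted p = 2.27e-05 (Bbc3). That of their effector Bax rose by 1.51 ± 0.17, adjusted p = 3.44e-07, and Bcl2l11, the gene of the BH3-only protein BIM, by 2.11 ± 0.21, adjusted p = 6.94e-08. Ccng1, which encodes cyclin G1, rose by 3.05 ± 0.23, adjusted p = 2.71e-10. Myc, whose product drives these tumours, rose by 0.35 ± 0.14, adjusted p = 0.039, a call lost without line 287 or 621 or any 1 of their 4 control libraries. Counts on Myc can hold transcripts of both the endogenous gene and the transgene, which are not told apart. In GRCm38, Cdkn1a (NCBI gene 12575) lies on chromosome 17, 29090979 to 29100722, and Mdm2 (17246) on chromosome 10, 117688875 to 117710758. In all, 5260 of 12321 genes changed, 2694 up and 2566 down. The count was 1423 without the block for cell line, 2942 with only the control libraries, 2758 without line 287 and 3240 without the untreated 287 library of the control.

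The largest rises in the control included genes of the antiviral response. Ifit1, which binds viral RNA, went from 3 counts in the 3 untreated libraries to 8675 (ratio 2820, 95% interval 964 to 13700). Rsad2, which encodes the antiviral enzyme viperin, went from 2 to 3229 counts (1570, 435 to 13000), and Oasl1, an oligoadenylate synthetase-like gene, from 3 to 3257 (1060, 362 to 5130). Ifit2 rose by 6.90 ± 0.89, adjusted p = 2.85e-06, and Ifih1, the gene of the RNA sensor MDA5, by 6.38 ± 0.95, adjusted p = 1.78e-05. Ephx1, an epoxide hydrolase, rose by 6.46 ± 1.04, adjusted p = 4.4e-05, the chemokine receptor-like gene Ccrl2 by 5.98 ± 0.68, adjusted p = 3.61e-07, and Atf3, a stress transcription factor, by 5.85 ± 0.97, adjusted p = 5.51e-05. The largest falls included Ankrd37 (-3.87 ± 0.35, adjusted p = 8.12e-09) and the mitophagy gene Bnip3 (-2.38 ± 0.52, adjusted p = 0.000919), both known to be induced by hypoxia. Eml1 (-2.56 ± 0.58), Rsph9 (-2.36 ± 0.39), Crip1 (-2.23 ± 0.52), the fatty acid binding gene Fabp5 (-2.19 ± 0.62), the Notch-modifying gene Lfng (-2.17 ± 0.30), Camk4 (-2.08 ± 0.43) and Aldh1b1 (-2.08 ± 0.48) also fell. Of these, Eml1 lost its call without 287, Crip1 without 621 and Fabp5 without either.

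The p53 target lists moved up in the control. Of 15 measured apoptosis targets, 13 rose and none fell (median log2 2.81, camera adjusted p = 8.01e-11, and adjusted p = 0.0622 with an estimated correlation). Ei24 (1.65 ± 0.16) and Trp53inp1 (2.81 ± 0.31), which encodes a partner of p53 in stress, were among them. Fas, a death receptor gene, went from 0 to 349 counts, at least 113-fold higher. Phlda3, an inhibitor of AKT, went from 2 to 1452 counts (ratio 707, 195 to 5850), and the receptor gene Eda2r from 1 to 343 (334, 59.6 to 13200). Of 12 arrest targets 8 rose and 1 fell (median 1.42, camera adjusted p = 5.11e-05, and adjusted p = 0.0622 with an estimated correlation), with Plk2 at 3.95 ± 0.31, Psrc1 at 4.37 ± 0.44 and Gtse1 at 2.29 ± 0.26. Among 6 feedback genes 5 rose and 1 fell (median 1.94, camera adjusted p = 0.000131, and adjusted p = 0.146 with an estimated correlation). Mdm4, which restrains p53, rose by 2.0 ± 0.30, the ubiquitin ligase gene Rchy1 by 1.87 ± 0.32 and the phosphatase gene Ppm1d by 1.26 ± 0.22, while Cop1, also a ubiquitin ligase for p53, fell (-0.46 ± 0.17). Of 15 metabolic targets 9 rose and 2 fell (median 0.54, camera adjusted p = 0.0168, and adjusted p = 0.0622 with an estimated correlation). Sesn2 (4.06 ± 0.48), Lpin1 (4.57 ± 0.70) and Acad11 (1.51 ± 0.24) rose, and Ak1, an adenylate kinase gene, went from 2 to 1071 counts (522, 144 to 4310). Of 19 other targets 16 rose and 1 fell (median 2.75, camera adjusted p = 8.01e-11, and adjusted p = 0.0622 with an estimated correlation). Among those that rose were the T cell costimulator Cd80 (6.88 ± 0.55), Zfp365 (7.26 ± 0.69), Fam212b (5.44 ± 0.38) and Exoc4 (2.59 ± 0.26). The DNA repair list did not pass the test (camera adjusted p = 0.0564, and adjusted p = 0.146 with an estimated correlation), with 5 of 13 members up and 1 down. The excision repair nuclease gene Ercc5 rose by 3.62 ± 0.31, the translesion polymerase gene Polk by 2.54 ± 0.29 and Rrm2b by 1.06 ± 0.19, and Polh fell (-0.52 ± 0.10). Adjusted over the list alone, the counts up and down were 13 and 0 for apoptosis, 8 and 1 for arrest, 5 and 1 for feedback, 9 and 2 for metabolism, 16 and 1 for other targets and 5 and 1 for repair genes. Cop1 lost its call without 287 or 621 and without any 1 of 4 control libraries (untreated AH47A, nutlin 287 and both of 621).

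Interferon, NF-kB and ATF4 stress genes also rose in the control. Of 25 measured interferon response genes 24 rose and none fell (median log2 4.26, or 4.22 with the genes at 0 counts put at their bound, camera adjusted p = 8.01e-11, and adjusted p = 0.146 with an estimated correlation). Isg15, a ubiquitin-like modifier, went from 1 to 861 counts (ratio 839, 150 to 33200), and the antiviral GTPase gene Mx1 from 1 to 398 (388, 69.2 to 15400). Ifit3 went from 0 to 485 and Rtp4 from 0 to 484 counts, each at least 157-fold higher, and Bst2, which encodes tetherin, rose by 1.41 ± 0.15. Of 15 NF-kB targets 12 rose and none fell (median 2.35, camera adjusted p = 4.26e-07, and adjusted p = 0.146 with an estimated correlation). Rel rose by 2.35 ± 0.26, Relb by 4.06 ± 0.53, Nfkb2 by 3.13 ± 0.43, the inhibitor gene Nfkbia by 1.72 ± 0.21 and Tnfaip3, which encodes the brake A20, by 5.01 ± 0.73. Bcl3 went from 0 to 165 counts, at least 53.6-fold higher. Of 20 ATF4 stress genes 16 rose and none fell (median 1.84, camera adjusted p = 2.73e-08, and adjusted p = 0.146 with an estimated correlation), among them Ddit3, the gene of the death-linked factor CHOP (3.30 ± 0.40), Cebpb (2.25 ± 0.28) and Trib3 (5.22 ± 0.67). In line 287 the summed myeloid markers stood at 23 CPM untreated and 52.1 CPM after nutlin and the summed T cell markers at 6.46 and 20.7 CPM (means of 6 constructs). Most of each sum was 1 gene there, with Itgam at 40 of 56.2 CPM and Zap70 at 18.8 of 22.1 CPM in the nutlin library of the control. In AH47A the sums were 9.25 and 18.5 CPM (myeloid) and 5.82 and 6.76 CPM (T cell), and in 621 they were 14.2 and 16.9, and 0.332 and 0.449 CPM. Of 4 measured myeloid markers 2 rose, the integrin gene Itgam (2.38 ± 0.37) and the lysosomal gene Cd68 (1.16 ± 0.26), with a list median of 0.79 (camera adjusted p = 0.146). Of 3 T cell markers 1 rose, the kinase gene Zap70 (1.68 ± 0.52, camera adjusted p = 0.341). Adjusted over the list alone, the counts up and down were 24 and 0 for interferon, 12 and 0 for NF-kB, 16 and 0 for ATF4 stress, 2 and 0 for myeloid and 1 and 0 for T cell genes. Cd68 lost its call without 287, and Zap70 without 287 or the control's untreated 287 library. Ifit1 (NCBI gene 15957) lies on chromosome 19, 34640889 to 34650009 of GRCm38.

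Genes of sterol synthesis, DNA replication and growth moved down. Of 21 mevalonate genes 20 fell (median -1.18, camera adjusted p = 2.73e-08, and adjusted p = 0.171 with an estimated correlation). Sqle, squalene epoxidase, fell (-1.56 ± 0.30), as did Hmgcs1 (-1.27 ± 0.22), Insig1 (-1.20 ± 0.18) and Msmo1 (-1.06 ± 0.16). Of 38 DNA replication genes 23 fell and 1 rose (median -0.38, camera adjusted p = 1.26e-08, and adjusted p = 0.0622 with an estimated correlation). The transcription factor genes E2f1 (-0.84 ± 0.09) and E2f2 (-1.30 ± 0.18), the polymerase clamp gene Pcna (-0.97 ± 0.12) and Uhrf1 (-1.07 ± 0.15) were among those that fell. Of 35 mitosis genes 12 fell and 1 rose (median -0.37, camera adjusted p = 0.00231, and adjusted p = 0.46 with an estimated correlation). The mitotic kinase gene Cdk1 (-0.90 ± 0.23), Ccna2 (-0.67 ± 0.18) and Kif20a (-0.95 ± 0.28) fell, and the kinetochore gene Ndc80 rose (0.80 ± 0.18). Of 29 MYC and ribosome biogenesis genes 12 fell and 1 rose (median -0.31, camera adjusted p = 0.00111, and adjusted p = 0.382 with an estimated correlation), with the transferrin receptor gene Tfrc at -0.87 ± 0.18, Cdk4 at -0.74 ± 0.16 and the glycolysis gene Ldha at -1.51 ± 0.32. Of 35 proteasome genes 11 fell and 1 rose (median -0.28, camera adjusted p = 0.0185, and adjusted p = 0.464 with an estimated correlation). Nfe2l1, the transcription factor gene of the list, rose (1.06 ± 0.14), and the subunit gene Psmd7 fell (-0.54 ± 0.15). Of 11 early B lineage genes 4 fell (median -0.94, camera adjusted p = 0.0474, and adjusted p = 0.296 with an estimated correlation), among them Sox4 (-0.94 ± 0.25), the recombinase gene Rag2 (-1.42 ± 0.40) and Igll1 (-1.54 ± 0.58). Adjusted over the list alone, the counts up and down were 0 and 20 for mevalonate, 1 and 25 for replication, 1 and 11 for mitosis, 1 and 12 for MYC and ribosome, 1 and 11 for proteasome and 0 and 4 for early B lineage genes. Kif20a lost its call without 621 or either control library of 287, Ccna2 without AH47A and Cdk1 without 621. Sox4 lost its call without 287 or the control's nutlin 287 library, and Rag2 without 287 or either control library of it. Igll1 lost its call without 621, either control library of 287 or the untreated AH47A control.

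Genes of cell survival and of later B cell stages moved both ways in the control, and their lists did not pass the test. In the BCL2 family 5 of 13 genes rose and 4 fell (camera adjusted p = 0.341). Its median was -0.27 while its mean, 0.88, and its test were positive, and Bak1 (-0.84 ± 0.17), which permeabilises mitochondria, and Mcl1 (-0.51 ± 0.11), which guards them, fell. Of 18 mature B cell genes 2 rose and 5 fell (median -0.05 with a positive mean, 0.20, camera adjusted p = 0.528). The activation marker gene Cd69 rose (4.39 ± 0.35), and the B cell receptor genes Cd22 (-0.62 ± 0.11) and Cd79a (-0.90 ± 0.16) fell. Of 5 plasma cell genes 1 fell, Derl3 (-1.43 ± 0.45), with a list median of -0.47 (camera adjusted p = 0.258). The 1 measured erythroid marker, Hbb-b1, was called lower and had 0 counts in the control after nutlin (log2 -1.91 at its bound, camera adjusted p = 0.341). The 1 measured fibroblast marker, Tagln, was at -0.80 ± 0.39 (camera adjusted p = 0.528). Adjusted over the list alone, the counts up and down were 5 and 5 for the BCL2 family, 2 and 5 for mature B, 0 and 1 for plasma, 0 and 1 for erythroid and 0 and 1 for fibroblast genes. Derl3 lost its call without 287, 621 or the control's nutlin 287 library, and Hbb-b1 without either control library of 621. Of the 22 lists, camera called 14 in the control response, 0 with an estimated correlation, and fry called 18.

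These targets also rose in cells with each mutant protein. The log2 response of Cdkn1a was 6.16 in G280, 6.70 in I192S, 6.43 in R246Q, 6.42 in R270H and 6.24 in V170M (SE 0.52 in G280). That of Mdm2 was 1.88 in G280, 1.93 in I192S, 1.88 in R246Q, 2.08 in R270H and 1.57 in V170M (SE 0.27 in G280). In the same order, Pmaip1 rose by 5.47, 5.54, 5.68, 6.01 and 5.25, Bbc3 by 4.68, 4.24, 4.0, 4.10 and 4.21 and Bax by 1.33, 1.38, 1.32, 1.34 and 1.28. Ccng1 rose by 2.88, 2.92, 2.73, 3.01 and 2.72 and Bcl2l11 by 1.53, 1.63, 1.58, 1.51 and 1.30. Myc did not pass the test in any mutant (0.32, 0.27, 0.25, 0.34 and 0.26). Neither did Trp53 itself, at -0.41, -0.38, -0.49, -0.55 and -0.25 (adjusted p from 0.0589 in R270H to 0.497 in V170M), against 0.47 ± 0.22, adjusted p = 0.0844 in the control. Nutlin changed 2144 genes with G280 (1318 up, 826 down) and 3065 with I192S (1680 up, 1385 down, or 1799 and 1218 of the calls with DESeq2's size factors). It changed 2656 genes with R246Q (1497 up, 1159 down), 3715 with R270H (1948 up, 1767 down) and 1013 with V170M (711 up, 302 down), and these counts are not tests of a difference from the control. Without the block for cell line they were 168, 245, 205, 400 and 68, and without line 287 they were 267, 856, 769, 1173 and 196. They were 1275, 1183, 858, 1088 and 578 without line 621, and 130, 380, 1159, 1141 and 244 with the groups compared alone. Leaving out a mutant's own untreated or nutlin 287 library gave 527 and 488, 1086 and 1098, 888 and 1090, 1595 and 1912, and 291 and 316. Leaving out the nutlin 621 library gave 1879 with I192S, 1535 with R246Q and 2319 with R270H, and leaving out the untreated 621 library gave 611 with V170M.

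On the log2 scale, mutant cells kept most of the control's induction of p53 targets. Over the 54 of 77 measured p53 targets that rose in the control, the median share of the control's log2 response was 76% with G280, 81.1% with I192S, 74.6% with R246Q, 78.8% with R270H and 69.2% with V170M. Computed within each line it was 74.3 ± 12.6, 76.4 ± 19.1, 73.6 ± 9.2, 76.6 ± 14.8 and 66 ± 12.7% (mean ± SD, n = 3). Between 48 (I192S) and 52 (R270H) of the 54 genes lay below the control. Choosing the genes in the control libraries favours a high control value, and over 55 genes chosen in the mutant libraries instead the control's response was 131.3% of the mutants' (within lines 168.9% in AH47A, 116.8% in 287 and 134.9% in 621, mean 140.2%). Cdkn1a kept 96.6% and Zmat3, an RNA-binding p53 target, 102.4% as the mean of 5 mutants. Mdm2 kept 73%, Mdm4 55.3%, the apoptosome gene Apaf1 54.7% and Pidd1 52.4%, and Zmat3, Apaf1 and Pidd1 were chosen after their values were seen. By list the median was 79.5% for 8 arrest genes, 83.4% for 13 apoptosis genes, 70.1% for 4 feedback genes, 75.3% for 4 repair genes, 54.8% for 9 metabolic genes and 72.9% for 16 others. The lists did not differ past the threshold (permutation test over genes, p = 0.0652). Across genes, which are not independent replicates, the share rose with the size of the control's response (Spearman's rho 0.711, Pearson's r 0.631, 54 genes). The permutation p was 1e-05 for both, the smallest that 100000 resamples can give. Such a trend also arises by arithmetic where every gene keeps the same share of its increment in CPM. Fas, Phlda3, Ak1 and Eda2r, which had the largest fitted responses in the control, had 0 to 2 untreated counts there. Their sizes and shares are therefore uncertain and entered as fitted. The median log2 response of these targets within a line was 2.54 ± 0.52 in the control (mean ± SD over the 3 lines). It was lower with each mutant in 3 of 3 lines. Mutant minus control of these medians was -0.68 ± 0.28 for G280, -0.61 ± 0.59 for I192S, -0.70 ± 0.25 for R246Q, -0.53 ± 0.53 for R270H and -0.92 ± 0.30 for V170M. With 3 lines no exact two-sided test of the sign can fall below p = 0.25. On increments in CPM instead of logarithms, an alternative chosen after the data were seen, the shares were 58.4, 61.1, 55.5, 66.3 and 43.5%. Within lines these were 46, 30.2, 42.8, 38.4 and 30.3% in AH47A, 68.3, 70.6, 63.3, 77.5 and 47.8% in 287 and 39.6, 80.2, 53.8, 60.8 and 43.9% in 621. On that scale Cdkn1a kept 58.6%, Mdm2 58.7%, Pmaip1 77.4%, Fas 36.6% and Ak1 35.1%.

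**Figure D2:**
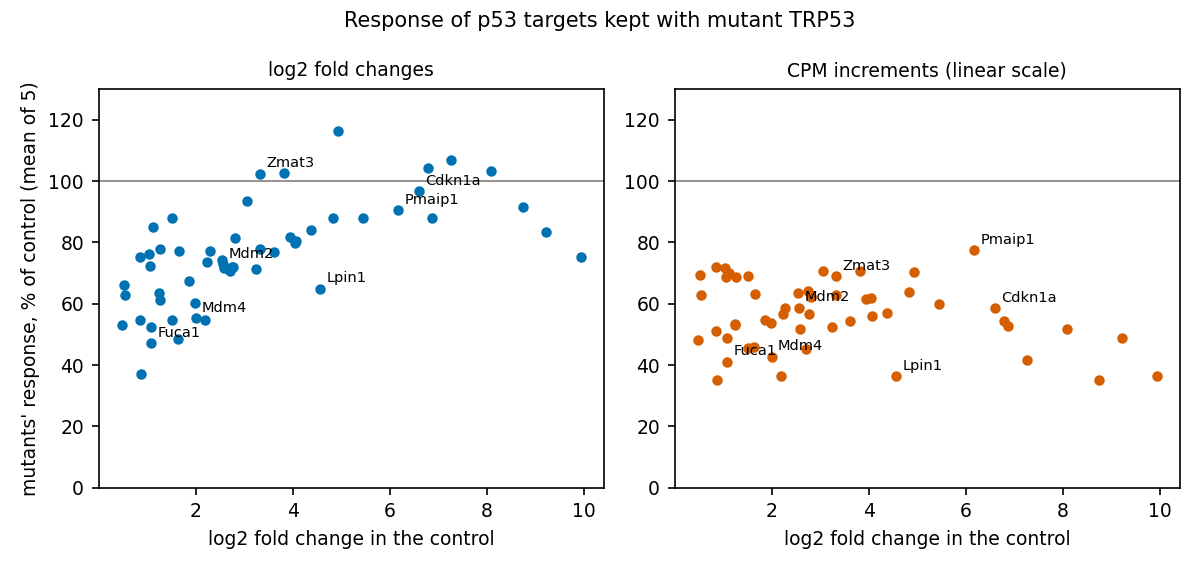
Share of the control's nutlin response that mutant cells kept, for each p53 target that rose in the control (points, mean of 5 mutants, in percent), against the control's log2 fold change. The left panel uses log2 fold changes, where the share rises with the size of the response (Spearman's rho 0.711 across 54 genes), and the right panel uses increments in CPM (rho -0.102).

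In nutlin-treated cells, p53 targets were lower and DNA replication genes higher with the mutants than in the control, taken as the mean of 5 mutants. Fas (-1.68 ± 0.26, adjusted p = 0.00696), Phlda3 (-1.24 ± 0.23, adjusted p = 0.00909), Eda2r (-1.49 ± 0.30, adjusted p = 0.0308) and Ak1 (-1.70 ± 0.26, adjusted p = 0.00483) were lower. So were the carbonyl reductase gene Dcxr (-1.02 ± 0.24, adjusted p = 0.0385), Mdm4 (-0.89 ± 0.21, adjusted p = 0.0389) and Bcl2l11 (-0.61 ± 0.15, adjusted p = 0.0466). Cdkn1a (-0.89 ± 0.27, adjusted p = 0.104), Mdm2 (-0.72 ± 0.19, adjusted p = 0.065), Bax (-0.42 ± 0.12, adjusted p = 0.0979) and Ccng1 (-0.51 ± 0.16, adjusted p = 0.111) were not called. E2f1 (0.49 ± 0.07, adjusted p = 0.00213), the histone mRNA gene Slbp (0.52 ± 0.10, adjusted p = 0.00844), Pcna (0.52 ± 0.10, adjusted p = 0.00909) and Uhrf1 (0.63 ± 0.12, adjusted p = 0.0137) were higher. The sterol synthesis gene Msmo1 (0.67 ± 0.13, adjusted p = 0.0125) and the fatty acid elongase gene Elovl6 (0.94 ± 0.23, adjusted p = 0.0469) were higher too. By list, 3 of 15 apoptosis targets were called lower, or 9 adjusted over the list alone (median -0.47, camera adjusted p = 1.8e-11, and adjusted p = 0.0506 with an estimated correlation). Of 19 other targets 4 were lower, or 14 adjusted over the list alone (median -0.70, camera adjusted p = 3.55e-13, and adjusted p = 0.0431 with an estimated correlation). Of 15 metabolic targets 3 were lower, or 5 adjusted over the list alone (median -0.27, camera adjusted p = 0.00045, and adjusted p = 0.0102 with an estimated correlation). Of 6 feedback genes 1 was lower, or 5 adjusted over the list alone (camera adjusted p = 0.000398, and adjusted p = 0.152 with an estimated correlation), and of 12 arrest targets 0 or 5 (camera adjusted p = 0.00045, and adjusted p = 0.0986 with an estimated correlation). Of 38 replication genes 5 were higher, or 18 adjusted over the list alone (median 0.21, camera adjusted p = 7.91e-18, and adjusted p = 0.00235 with an estimated correlation). Of 21 mevalonate genes 1 was higher, or 13 adjusted over the list alone (median 0.53, camera adjusted p = 2.5e-10, and adjusted p = 0.151 with an estimated correlation). No ATF4 stress gene was called, or 2 lower adjusted over the list alone (median -0.44, camera adjusted p = 4.55e-08, and adjusted p = 0.151 with an estimated correlation). No interferon gene was called (median -0.37, camera adjusted p = 0.00045, and adjusted p = 0.439 with an estimated correlation), nor any NF-kB target (median -0.21, camera adjusted p = 0.0149, and adjusted p = 0.439 with an estimated correlation), 0 in either list also adjusted over the list alone. The DNA repair list was not called, with 1 of 13 members lower, or 3 adjusted over the list alone (median -0.11, camera adjusted p = 0.0676, and adjusted p = 0.151 with an estimated correlation). Of the 22 lists camera called 10, of which 3 held with an estimated correlation. In all 123 genes differed, 30 higher and 93 lower. Among them were St14, a membrane protease gene (-1.40 ± 0.35, adjusted p = 0.0467), Lrrc28 (-1.03 ± 0.24), Kank3 (-0.93 ± 0.21), Hhex, a B cell transcription factor gene (0.62 ± 0.14), and Acss1 (0.78 ± 0.18). Of 38 named genes called and tested without AH47A, 2 kept the call (Trp53 and E2f1). Of 39 named genes called, 31 kept it without 287 and 1 without 621 (Fgf13). Without the control's nutlin library of AH47A, 287 or 621, 3 (Trp53, E2f1 and Pcna), 6 and 10 kept it. Elovl6, St14, Mdm4, Bcl2l11, Dcxr, Lrrc28, Hhex, Kank3 and Acss1 also lost their calls when 1 or more single mutant libraries were left out.

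Single mutants differed from the control under nutlin in 59 genes for V170M (14 higher, 45 lower), 2 for G280, 2 for I192S, 4 for R246Q and 1 for R270H. E2f1 was at 0.54 ± 0.09, adjusted p = 0.0126 with V170M, 0.52 ± 0.09, adjusted p = 0.0272 with G280 and 0.54 ± 0.09, adjusted p = 0.03 with R246Q. It was not called with I192S (0.45 ± 0.09, adjusted p = 0.0775) or R270H (0.40 ± 0.09, adjusted p = 0.195). V170M cells also had more Uhrf1 (0.78 ± 0.15, adjusted p = 0.0209) and less Adat2 (-0.84 ± 0.14, adjusted p = 0.0126). They had less Rev1, a translesion polymerase gene (-0.62 ± 0.11, adjusted p = 0.0142), and less Dnaja3, a mitochondrial chaperone gene (-0.70 ± 0.13, adjusted p = 0.0163). R246Q cells had more Slbp (0.62 ± 0.12, adjusted p = 0.0443) and less Gdpd5 (-0.91 ± 0.17, adjusted p = 0.0391). Each of these single-gene calls was lost without AH47A and without 621, and all but those of Uhrf1 and Dnaja3 also without 287. The remaining calls of G280, I192S, R246Q and R270H were Trp53 and, chosen after their values were seen, Wls with I192S and Nrp2 with R270H, which had counts in AH47A almost alone. None of these differences was called without the block for cell line in any mutant or in their mean, where 423 genes had an unadjusted p under 0.05 in edgeR. DESeq2 called 48, 2, 10, 12 and 174 genes for G280, I192S, R246Q, R270H and V170M and 209 for the mean of 5. The unfiltered table gave 1 for G280, 0 for R246Q, 39 for V170M and 74 for the mean. The 123 became 5 without AH47A, 263 without 287 and 3 without 621. Leaving out the control's nutlin library gave 5 (AH47A), 17 (287) and 20 (621). Leaving out the AH47A nutlin library of G280, R270H or V170M gave 57, 79 and 55, and leaving out the 287 nutlin library of G280 or R270H gave 217 and 279. For V170M the 59 became 12, 31 and 0 without AH47A, 287 and 621, 6, 19 and 22 without the control's nutlin library of each, and 2, 3 and 1 without its own. For G280 the 2 became 148 without 287, 37 without its nutlin 287 library, 0 without 621, and 1 without the AH47A control or its own 621 library. For I192S the count was 0 without 287, its own AH47A library or the control's 287 library, and 1 without AH47A or 621. For R246Q it was 0 or 1 in all 9 cases. For R270H it was 0 without AH47A, 621, or the AH47A nutlin library of either group, 14 without 287, 22 without its 287 library and 2 without the control's 621 library. Libraries of the groups compared alone gave 286, 0, 1275, 110 and 1159.

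A difference between a mutant's nutlin response and the control's was not called for any gene by edgeR in the additive model. At an unadjusted p under 0.05 there were 391 genes for G280, 324 for R246Q, 359 for R270H, 700 for V170M and 680 for the mean of 5, and 1.56% of the genes tested for I192S. DESeq2 called 0, 1, 0, 0, 1 and 1 for the 5 mutants and their mean. The count was 1 for G280 and the mean without 287, 1 for R246Q and the mean without the control's nutlin 621 library, and 1 for R270H without its untreated 287 library. By list, 36 of 38 replication genes had a positive difference, so that they fell less or rose more with the mutants (median 0.23, camera adjusted p = 1.75e-16, and adjusted p = 0.0037 with an estimated correlation), with 0 called and 7 adjusted over the list alone. The list passed with an estimated correlation in each mutant as well (adjusted p from 0.00532 in G280 to 0.0437 in R270H), though in the line-specific response fit R270H was at adjusted p = 0.0602 with an estimated correlation. Of 21 mevalonate genes 20 were positive (median 0.44, camera adjusted p = 9.53e-07, and adjusted p = 0.298 with an estimated correlation), and of 20 ATF4 stress genes 0 (median -0.48, camera adjusted p = 7.95e-07, and adjusted p = 0.298 with an estimated correlation). The apoptosis (median -0.39, camera adjusted p = 0.000206, and adjusted p = 0.298 with an estimated correlation) and other p53 targets (median -0.55, camera adjusted p = 0.000183, and adjusted p = 0.298 with an estimated correlation) had a lower response. So had the feedback (median -0.45, camera adjusted p = 0.00675, and adjusted p = 0.298 with an estimated correlation) and metabolic targets (median -0.22, camera adjusted p = 0.0163, and adjusted p = 0.0953 with an estimated correlation). The interferon list was not called (median -0.38, camera adjusted p = 0.267). Camera called 7 of the 22 lists, 11 without line 287, and 1 each with an estimated correlation and by fry.

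In the line-specific response fit, chosen after the data were seen, 416 genes responded differently with the mean of 5 mutants than in the control, 228 with a higher and 188 with a lower response. The response of Elovl6 was higher by 0.97 ± 0.12, adjusted p = 0.000128. Mdm2 (-0.71 ± 0.14, adjusted p = 0.00922), Mdm4 (-0.89 ± 0.15, adjusted p = 0.00371), Bcl2l11 (-0.58 ± 0.15, adjusted p = 0.0309) and the receptor gene Notch1 (-0.97 ± 0.21, adjusted p = 0.0128) had a lower response. So had the ATF4 targets Chac1, which degrades glutathione (-2.04 ± 0.39, adjusted p = 0.00617), Ddit4 (-0.90 ± 0.19, adjusted p = 0.0101) and Asns, asparagine synthetase (-0.44 ± 0.10, adjusted p = 0.0128). Pcna (0.56 ± 0.08), Uhrf1 (0.55 ± 0.09), E2f1 (0.50 ± 0.09) and Sqle (0.61 ± 0.11) had a higher response. Cdkn1a (-0.21 ± 0.34, adjusted p = 0.822) and Bax (-0.19 ± 0.10, adjusted p = 0.31) were not called. Of 38 replication genes 8 were higher, or 22 adjusted over the list alone (camera adjusted p = 3.38e-15, and adjusted p = 0.00653 with an estimated correlation). Of 21 mevalonate genes 7 were higher, or 13 adjusted over the list alone (camera adjusted p = 6.42e-12, and adjusted p = 0.106 with an estimated correlation). Of 20 ATF4 stress genes 5 were lower, or 10 adjusted over the list alone (camera adjusted p = 3.13e-09, and adjusted p = 0.106 with an estimated correlation). By mutant there were 448 genes for V170M (223 higher, 225 lower), 22 for G280 (19 and 3), 3 for R246Q, 1 for I192S and 0 for R270H, which had 1325 at an unadjusted p under 0.05. The 416 became 64 without AH47A, 3 without 287 and 75 without 621. They became 70, 106 and 205 without the control's untreated AH47A, 287 and 621 library and 157 without its nutlin 621 library. Of 73 named genes called in this fit, 17 kept the call without AH47A, 3 without 287, Elovl6 and Dcaf4 among them, and 22 without 621. Without the control's untreated AH47A, 287 or 621 library 24, 28 and 44 kept it, and without its nutlin library 42, 58 and 41. For V170M the count was 2 without 287 and 72 without 621, and lay between 93 and 689 when single libraries were left out. For G280 it lay between 0 and 208, for I192S between 0 and 51, for R246Q between 0 and 12 and for R270H between 0 and 70. Under nutlin the same fit called 1969 genes for the mean of 5 (890 higher, 1079 lower). They were 1200, 1055 and 982 without AH47A, 287 and 621, and 1086 and 1023 without the control's nutlin AH47A and 621 library. In GRCm38, Elovl6 (NCBI gene 170439) lies on chromosome 3, 129532386 to 129638495, Mdm4 (17248) on chromosome 1, 132986105 to 133030587 and Chac1 (69065) on chromosome 2, 119351242 to 119354326.

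Before treatment, Trp53 was the gene called in all 5 mutants, and hardly any other gene differed from the control. For G280, I192S, R246Q and V170M it was the 1 call, and for R270H and for the mean of 5 there were 2. The added genes were Nrp2, a semaphorin receptor gene, for R270H and Fgf13, a growth factor homologue gene, for the mean (-3.88 ± 0.47, adjusted p = 0.0176). They were chosen after their values were seen and had counts in AH47A almost alone, with 64 counts of Fgf13 in the untreated AH47A control, 120 with R246Q and 0 to 2 with G280, I192S and V170M. The call of Fgf13 was lost without 287 and without the untreated AH47A library of the control or of any mutant, and it was not tested without AH47A. At an unadjusted p under 0.05 there were 134, 173, 103, 187, 130 and 133 genes for G280, I192S, R246Q, R270H, V170M and the mean of 5, and DESeq2 called 1, 2, 1, 1, 1 and 1. Cdkn1a (-0.66 ± 0.49, adjusted p = 1), Mdm2 (-0.03 ± 0.21, adjusted p = 1) and Myc (-0.05 ± 0.11, adjusted p = 1) were not called in the mean of 5. In the mean of 5 the mevalonate list was the 1 list called by camera, with all 21 members positive and 0 called, 0 also adjusted over the list alone (median 0.06, camera adjusted p = 0.024, and adjusted p = 0.926 with an estimated correlation). By mutant, camera called 3 lists for R246Q (mevalonate and mature B cell genes up, MYC and ribosome genes down), 2 for R270H (mevalonate genes up, MYC and ribosome genes down) and 0 for the others, and 0 in each with an estimated correlation (adjusted p = 0.992 for the lists of R246Q and adjusted p = 0.959 for those of R270H). The mevalonate list of the mean was not called by fry, without AH47A, or without the block, each of which called 0 lists. Without the block for cell line Trp53 was called for G280, V170M and the mean and not for I192S, R246Q and R270H. Counts were 2 for G280 without AH47A or 287, and 2, 0 and 4 for I192S without AH47A, 287 and 621. They were 2 for R246Q without AH47A, 1 for R270H without AH47A, 621 or the untreated AH47A library of either group, and 4 for the mean without the control's untreated 287 library.

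The 5 mutants were also compared with one another. No gene differed among them in its nutlin response by edgeR (63 at an unadjusted p under 0.05, DESeq2 0, line-specific response fit 0). Nor did any in the 10 pairs of mutants, where 45 to 302 genes had an unadjusted p under 0.05. Untreated, 4 genes differed, all named after their values were seen. They were Wls, a Wnt secretion gene (adjusted p = 0.00489), Nrp2 (adjusted p = 0.00489), Fgf13 (adjusted p = 0.00759) and the immunoglobulin segment Igkv8-28. Wls had 131, 9, 119, 147 and 9 counts in the untreated AH47A libraries of G280, I192S, R246Q, R270H and V170M and 81 in the control, and Nrp2 had 170 in AH47A with R270H. DESeq2 called 1, the line-specific response fit 10 and the fit without the block 0. The count was 7 without 287, 2 without 621, 1 without the untreated AH47A library of I192S and 2 without the untreated 621 library of V170M. Under nutlin 5 of the 10 pairs had a call, with 1 gene each for I192S and G280, V170M and G280, R246Q and I192S, and R270H and I192S. In the line-specific response fit these pairs had 2, 0, 1 and 2, and V170M and R246Q had 1. Between V170M and R270H 2 genes differed, with 912 at an unadjusted p under 0.05, and in the line-specific response fit 372 differed, with 2438 at an unadjusted p under 0.05. These pairs were not tested with libraries left out.

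The 3 lines responded to nutlin differently, in the mean of the 6 constructs. The DNA damage kinase gene Atm rose by 0.55 in AH47A, 2.72 in 287 and 0.60 in 621. The growth factor gene Gdf11 rose by 0.88, 6.54 and 0.60, and the glycine transporter gene Slc6a9 by 1.06, 4.87 and 1.58. The mitotic genes Plk1 (-0.26, -1.49 and -0.51) and Kif20a (-0.29, -1.57 and -0.45) fell most in 287. In the same order, Cdkn1a rose by 8.27, 6.58 and 5.34, Mdm2 by 1.64, 2.66 and 1.64, and Ifit1 by 10.19, 10.77 and 10.32. The median log2 response of the interferon list was 2.16 ± 0.54 in AH47A, 4.80 ± 0.49 in 287 and 2.46 ± 0.92 in 621 (log2 CPM with a prior count of 2, mean ± SD of 6 constructs). The prior count shrinks these weakly expressed genes, and the medians of the values fitted by edgeR were 2.80, 7.29 and 4.23, with 23, 25 and 23 of 25 genes called up. The myeloid marker sum stood at 23 CPM before and 52.1 CPM after nutlin in 287, at 9.25 and 18.5 in AH47A and at 14.2 and 16.9 in 621. The T cell marker sum stood at 6.46 and 20.7 CPM in 287, 5.82 and 6.76 in AH47A and 0.332 and 0.449 in 621. Itgam was the largest part of the myeloid sum and Zap70 of the T cell sum in the nutlin libraries of 287. The median of the apoptosis targets was 1.71 ± 0.56, 3.0 ± 0.28 and 1.61 ± 0.35, and that of NF-kB targets 1.43 ± 0.33, 2.49 ± 0.09 and 1.56 ± 0.15. ATF4 stress genes were at 0.56 ± 0.40, 1.89 ± 0.41 and 1.15 ± 0.44, and mevalonate genes at -0.36 ± 0.19, -1.18 ± 0.18 and -0.75 ± 0.29. Mitosis genes were at -0.08 ± 0.04, -0.78 ± 0.09 and -0.09 ± 0.08, with 13, 32 and 14 of 35 called down. Nutlin changed 5371 genes in AH47A (2635 up, 2736 down), 8862 in 287 (4466 up, 4396 down) and 6776 in 621 (3254 up, 3522 down), with 1519 up and 1302 down in all 3 lines. By F test 7428 genes differed among lines in their response, with 3449 between AH47A and 621 when 287 was left out. Constructs served as replicates within a line, so this test speaks of these 3 lines.

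**Figure D3:**
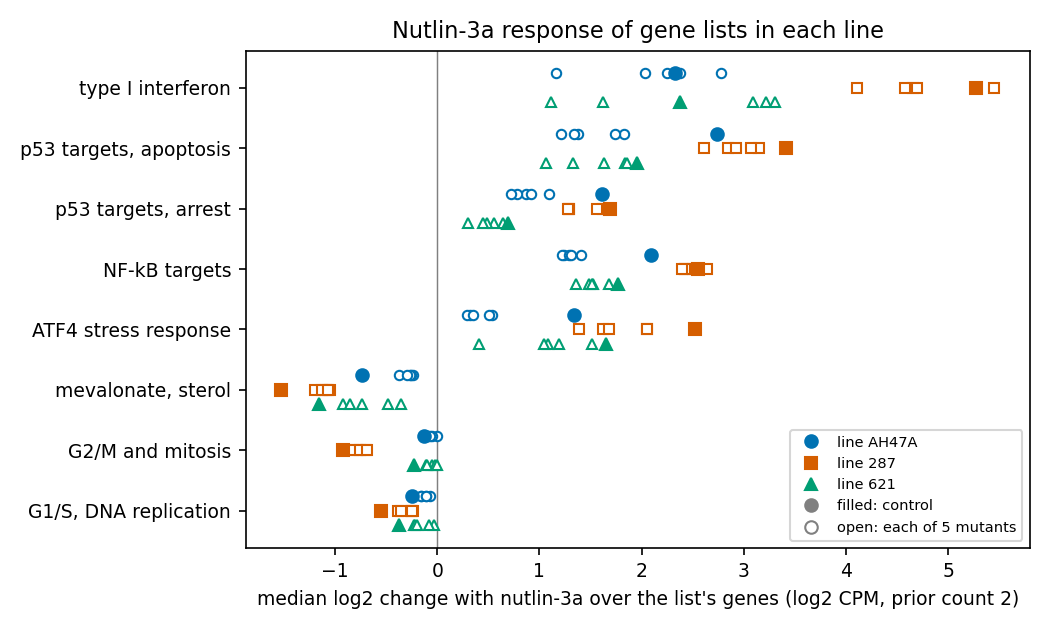
Median log2 change with nutlin of 8 gene lists (log2 CPM, prior count 2) in lines AH47A, 287 and 621; filled points are the control and open points the 5 mutants. The interferon list lies highest in 287 (mean 4.80 over 6 constructs, against 2.16 in AH47A and 2.46 in 621, values shrunk by the prior count, where the medians of fitted values are 7.29, 2.80 and 4.23).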

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

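Chosen only after their results were seen were the test of a stronger response of 287 in every gene, the comparisons with other splits of the libraries, and all tests of mutants against the control in the line-specific response fit, while its test of the lines was planned.

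The 3 lines differed in their nutlin response in 7428 genes, with 5780 between 287 and AH47A, 3893 between 621 and AH47A and 5102 between 621 and 287. A difference in depth is argued against, since 6886 genes still differed with every library thinned to 5404113 counts. Of the 5780 genes that differ between 287 and AH47A, 35.2% had a smaller or opposite response in 287. That share includes estimates of opposite sign without a call in AH47A, so it can be too high. It therefore does not decide by itself whether the response of 287 is stronger in every gene. Of 4545 genes called in both lines, 314 moved in opposite directions, which argues against that for these genes. The test of one shared programme run at different strengths did not decide. Of the genes called in both 287 and AH47A, 6.91% moved in opposite directions, between the bounds of 5% and 20% set for it. Opposite directions were seen in 492 of 3533 genes called in both 621 and AH47A (13.9%), and in 430 of 5586 for 621 and 287. For the genes called in opposite directions these values argue against a difference of strength alone, which stays open for the others. That the lines carry different lesions or stand at different B cell stages may explain differences between them, as a hypothesis that was not tested here.

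The 10 genes with the lowest p for a difference among lines were picked out because the lines' responses differ. Set as 287 minus AH47A on the log2 scale, the mitosis genes Kif20a and Plk1 were at -1.29 and -1.24, the kinase gene Atm at 2.17, Gdf11 at 5.66 and Slc6a9 at 3.81. Sec24b, a gene of vesicle transport, was at 1.73, the nuclear receptor coactivator gene Ncoa3 at 1.30 and the protein disulfide isomerase gene Pdia6 at -1.08. Tmtc4 was at 2.80 and Swap70, a B cell signalling gene, at 2.18. In 621 the responses were 0.60 for Atm, 0.60 for Gdf11, 1.58 for Slc6a9, 0.49 for Swap70 and 1.90 for Tmtc4. Other splits of the libraries into 3 sets gave at most 1240 genes against the real 7428 (1 of 100 splits). Chance among these cultures is therefore made unlikely, with the constructs taken as replicates of a line. The labels name no independent repeat of a line. A line's own response therefore cannot be told apart from conditions that its cultures may have shared.

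The response of mutant cells differed from the control's, in the line-specific response fit, in 22 genes for G280, 1 for I192S, 3 for R246Q, 448 for V170M and 416 for the mean of 5. For the mean of 5 the highest of the other splits gave 4 genes, so chance is made less likely. Some splits of the mean of 5 keep the real control in part of the lines. For single mutants 10 splits are too few for a share under 0.05, and the highest other was 0 for G280 (22), I192S (1), R246Q (3), R270H (0) and V170M (448). In the additive model no gene was called for the mean of 5, a count that all 100 splits must reach, so they say nothing about chance there (highest other 2). The 10 splits of a single mutant are too few, with a highest other of 2 for G280, 1 for R246Q and 0 for I192S, R270H and V170M against a real count of 0 in each. Under nutlin the mean of 5 gave 123 genes against 6 in the highest other split, and 1969 against 1006 in the line-specific response fit. Chance is made less likely for both and is not excluded. The split with 1006 genes shows that the line-specific response fit can call many genes under other labels. For single mutants under nutlin the 10 splits are too few. Real counts and highest others were 2 and 0 (G280), 2 and 7 (I192S), 4 and 0 (R246Q), 1 and 4 (R270H) and 59 and 1 (V170M). In the line-specific response fit they were 1293 and 0, 328 and 71, 747 and 0, 448 and 69, and 2168 and 3. Splits of I192S with 7 and of R270H with 4 genes put both libraries of a line on the same side and point to a structure of the samples. With every line parted the highest were 1 and 1, and 4 and 0 in the line-specific response fit.

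For the nutlin response, 10 splits of 3 against 3 libraries are too few for a share under 0.05. Real counts and highest others were 5260 and 24 in the control, 2144 and 120 in G280, 3065 and 27 in I192S, 2656 and 12 in R246Q, 3715 and 14 in R270H and 1013 and 12 in V170M. With every line parted the highest others were 28 in G280 and 12 in R270H. Untreated, the 10 splits are too few as well, with real counts and highest others of 1 and 0 (G280), 1 and 2 (I192S), 1 and 1 (R246Q), 2 and 8 (R270H) and 1 and 0 (V170M). The 8 came from a split that keeps both libraries of a line together, and with every line parted the highest was 0 for each. For the mean of 5, 42 of 100 splits gave 2 genes or more and the highest 7, so chance is not excluded. For differences among the mutants in untreated cells chance is not excluded, as 97 of 100 splits gave as many (4 genes, highest other 10). For the response the count of 0 genes must be reached by all 100 splits, which therefore say nothing about chance (highest other 0), and differences under nutlin were not tested by splits. Of the list counts, the 7 lists of the response difference were reached in 4 of 100 splits, the real one included. That share is under 0.05, but another split gave 11 lists, so chance is made less likely and is not excluded. The 1 list of untreated cells was reached in 71 of 100 (highest other 6), so chance is not excluded there either. For the 14 lists of the control response the 10 splits are too few (highest other 15, or 13 with every line parted).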

How the results depend on the processing

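The CPM increments, the retained share from log2 CPM means with a prior count of 2, and the use of the line-specific response fit beyond the test of the lines were chosen only after the results were seen, and the other alternatives were planned. No called result changed direction under any alternative, and the cause of the changes was not tested. Of the calls of named genes, 6 were lost and 9 gained with DESeq2, which gave Fgf13 no adjusted p under nutlin. DESeq2's size factors lost 7, no filter on low counts 41 and no block 200. With only the groups compared 53 were lost and 20 gained, and with the line-specific response fit 2 and 79. Without AH47A, 287 and 621, 131, 156 and 165 were lost and 1, 16 and 0 gained.

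With DESeq2 the response difference gave 1 gene for I192S, V170M and the mean of 5, and the untreated difference 2 for I192S and 1 for R270H and the mean. The difference under nutlin gave 48 for G280, 10 for R246Q, 12 for R270H, 174 for V170M and 209 for the mean, and the mutants differed untreated in 1. DESeq2's size factors gave 14 for the response difference of G280 in the line-specific response fit. Without a filter on low counts, which adds genes to the adjustment, the difference under nutlin was 1 for G280, 0 for R246Q, 39 for V170M and 74 for the mean, and 291 for R270H in the line-specific response fit. With only the libraries of the groups compared, the spread was estimated from those libraries alone, with fewer residual degrees of freedom. The nutlin response then gave 2942 genes in the control and 130, 380, 1159, 1141 and 244 in G280, I192S, R246Q, R270H and V170M. The untreated difference then gave 5, 0, 4, 4 and 0, and the difference under nutlin 286, 0, 1275, 110 and 1159.

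The pairing through the cell line carries much of the count. With no block, the nutlin response gave 1423 genes in the control and 168, 245, 205, 400 and 68 in the mutants in the same order. The untreated difference gave 0 for I192S, R246Q and R270H and 1 for the mean, the difference under nutlin 0 for each mutant and the mean, and the mutants differed untreated in 0, with 0 lists called untreated. The block changed no other count by more than 1.5 times.

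The line-specific response fit called 4589, 5129, 4876, 5581 and 3598 genes for the nutlin response of the mutants. It called 22, 1, 3, 448 and, for the mean, 416 for the response difference (G280, I192S, R246Q, V170M), 1 for R270H untreated, and 10 for mutants differing untreated, with 2 lists untreated. Under nutlin it called 1293, 328, 747, 448, 2168 and 1969. With an estimated correlation camera called 0 lists for the control response, 1 for the response difference and 0 untreated, and fry called 1 for the response difference and 0 untreated. The retained share on CPM increments was 58.4% for G280, 61.1% for I192S, 55.5% for R246Q and 43.5% for V170M, and as a slope through the origin 91.2% for G280, 89.6% for R246Q and 85% for V170M.

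Leaving out lines or single libraries gave 2758 to 4853 genes for the nutlin response of the control and 267 to 2643, 856 to 3914, 769 to 2783, 1088 to 4148 and 196 to 1464 for G280, I192S, R246Q, R270H and V170M. The response difference stayed at 0 to 1 for G280, R246Q, R270H and the mean, and at 0 for I192S and V170M. In the line-specific response fit it was 0 to 208, 0 to 51, 0 to 12, 0 to 70, 2 to 689 and, for the mean, 3 to 618. Untreated it was 1 to 2 for G280, 0 to 4 for I192S, 1 to 2 for R246Q, 1 to 3 for R270H and 2 to 4 for the mean, and 1 to 7 genes differed among mutants. Under nutlin it was 0 to 148, 0 to 2, 0 to 1, 0 to 22, 0 to 31 and 3 to 279, and in the line-specific response fit 34 to 1484, 3 to 612, 83 to 591, 20 to 741, 792 to 1975 and 982 to 2172. The lines differed in 3449 to 7415 genes. There were 13 to 14 lists in the control response, 6 to 11 in the response difference and 0 to 2 untreated. The retained share was 64.1 to 81.2%, 74.9 to 88.9%, 67.6 to 78.1%, 70.5 to 87% and 61.9 to 75.6%. The lowest counts of the nutlin response came without line 287 in the control and 4 mutants, a fit with fewer libraries and residual degrees of freedom. Depth limits weakly expressed genes, as at 5404113 to 10718302 counts a library 14858 genes were not tested.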

Other observations

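Tests chosen only after their result was seen were that of the macrophage gene Lyz2 and the retained share on CPM increments. Beyond the comparisons above, genes of interferons themselves appeared with nutlin. Ifna4 had 0 counts in all 18 untreated libraries and 692 counts in the nutlin libraries, in 17 of 18, with 60 to 194 a library in 287, 2 to 14 in AH47A and 0 to 3 in 621. Ifnb1 went from 2 to 114 counts, of which 110 lay in 287, and Ifna2 from 0 to 11. Reads of Ifna genes cannot be assigned to one copy with certainty, and none of these genes was tested. Irf7, which amplifies the interferon response, went from 69 to 816 counts.

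B lineage marker sums moved apart between lines, as values without a test. Early B lineage genes summed to 1260 CPM untreated and 846 after nutlin in 287, 1100 and 759 in AH47A, and 743 and 856 in 621 (means of 6 constructs). The higher sum in 621 is not a rise of the list. Rag1 alone held 567 of 964 CPM in its nutlin control library. By edgeR 1 of 11 early B lineage genes was called up and 4 down in 621 (median log2 -0.204), against medians of -0.968 in 287 and -0.517 in AH47A. Plasma cell genes summed to 1100 and 636 CPM in 287, 595 and 637 in 621, and 656 and 606 in AH47A. Mature B cell genes summed to 4110 and 4740 CPM, 5750 and 5100, and 3470 and 3060 in that order. In the control of 287, Ighm alone went from 2130 to 3230 CPM while the sum went from 4340 to 4840 CPM. In 287, 6 of 18 mature B cell genes were called up and 6 down (median log2 0.015), so the higher sum is not a rise of the list.

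Interferon response genes rose with nutlin in every line. Myeloid cells in the treated cultures are argued against, because Lyz2, an abundant macrophage transcript, had 9 counts over the 18 nutlin libraries, where Ifit1 had 41274, and S100a8 had 0. Cells of another type in general stay open, as the summed myeloid markers changed by a median of 0.688 (log2, 18 culture pairs), between the bounds of 0.5 and 1 set for that test, and the T cell markers by 0.464, below both but with a range over pairs of -0.651 to 1.908. The sums can be carried by 1 gene. In the nutlin 287 library of I192S, Itgam held 49.3 of 65.1 CPM (myeloid) and Zap70 21.7 of 23.3 CPM (T cell). In 621, where 23 of 25 interferon genes rose, the mean sums went from 14.2 to 16.9 CPM (myeloid) and from 0.332 to 0.449 CPM (T cell). Whether the cells were sorted is not given in the sources used here. That interferon genes follow the strength of the p53 response is a hypothesis which 6 constructs a line cannot decide, with Spearman's rho between the list medians of 0.486 in AH47A (exact p = 0.356), 0.829 in 287 (exact p = 0.0583) and 0.6 in 621 (exact p = 0.242), median 0.6, adjusted p of 0.356, 0.175 and 0.356, Pearson's r of 0.275, 0.699 and 0.552 (exact p = 0.399, 0.114 and 0.251) and r of -0.05, 0.31 and 0.963 without the 2 farthest constructs. The caspase inhibitor cannot be told apart from nutlin, because 0 nutlin libraries are labelled as without the inhibitor, and cells that die without caspases may release nucleic acids that induce interferon, which stays untested.

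Mutant cells kept a smaller share of the induction of weakly than of strongly induced p53 targets, on the log2 scale. A constant share of the CPM increment by itself gives a log2 share that rises with the size of the response. The log2 trend alone therefore does not show that weakly and strongly induced targets are affected differently. Choosing the genes in the control libraries is argued against as the cause of the lower share, since over 55 genes chosen in the mutant libraries the control's response was still 131.3% of the mutants', and within lines 140.2 ± 26.4% (mean ± SD; 168.9, 116.8 and 134.9% in AH47A, 287 and 621). On CPM increments the share did not depend detectably on size across 54 genes (Spearman's rho -0.102, permutation p = 0.456, median 56.7%, quartiles 49.4 and 63.6%, genes not being independent replicates), as it would if a share of the cells did not respond. A uniformly lower p53 activity in every cell would give the same value, so these bulk libraries do not separate the 2, and a share of cells without a response may be followed up as a hypothesis.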
